A study of Mus musculus with 36 samples.

How the data were processed

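RNA of 36 muscle samples of C57BL10, mdx and mdx5cv mice was measured on MG_U74Av2 arrays (named in the experiment files), and the value table holds 12488 probe sets. The deposited values are linear signal intensities scaled per array by the authors: the 2% trimmed means of the columns lay between 1500 and 1501, within the tolerance of 10%, so the values were used as deposited. The signal algorithm is not given in the sources used here. Values under the 20th percentile of the table (a signal of 118) were set to it and log2 was taken. The 66 control probe sets served for RNA quality, and of the other 12422 those with a mean at or above the 40th percentile were tested, 7453 in all.

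Groups were taken from the sample titles and source names. In mdx EDL sample 1 the description names mdx5cv while title and source name mdx, and it was grouped as mdx. Leaving it out gave 949 probe sets for mdx against C57BL10, 32 for mdx5cv against mdx, 138 for mutant against C57BL10 EDL, 11 for the diaphragm against the limb muscles and 36 in the joint test. The comparisons were planned over all 36 columns, but 2 pairs of columns were equal in all 12488 probe sets, so 1 of each pair was left out. The copy named quadriceps was kept since it has an experiment file. Scan day and chip lot were read from the experiment files of 30 arrays, 14 days and 7 lots, and days more than 30 days apart were put in separate periods. The single array of the fourth period was joined to the third in the fixed block. No period holds 2 arrays of a group, so the fit of group means gives no test within a period for comparisons within a muscle. Arrays with a median Spearman correlation under 0.8 with the others were called low-correlation arrays, a limit chosen after the data were seen.

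A linear model with 18 group means was fitted with limma 3.58.1 in R 4.3.3 (16 residual degrees of freedom), with eBayes and a trend of the prior variance on intensity. Contrasts were the strains averaged over the 6 muscles with equal weight, both mutants against C57BL10 in each muscle, each C57BL10 muscle against the mean of the other 5, the change in the diaphragm against the mean change in the limb muscles, and a joint F test over the 6 muscles. Groups with 1 array were assumed to vary like the others. P-values are two-sided and were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined, save those said to be chosen later. The reading of old gene symbols through synonyms, which sets list members, and the form of the period model were corrected after first results were seen.

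The 33 gene lists of inflammation, matrix, repair, fibre proteins, metabolism, stress and markers of other cell types were tested with camera at a preset correlation of 0.01 and again with an estimated one. The platform annotation gave 1 symbol for 10855 probe sets, several for 396 and none for 1237. A gene is represented by its probe set with the highest mean over all columns, which gave 5695 tested genes, and the 731 tested probe sets without a symbol or with several were counted and not named. Dmd and Utrn are always named. In the averaged strain comparisons the 6 highest and 6 lowest genes past the threshold with the same direction in all 6 muscles are named, with up to 4 genes past it per list. In the other comparisons these are the 4 highest, the 4 lowest and up to 2 per list, of which the text gives a part, chosen after the data were seen and partly for length. None of the 632 pairs of a named gene and a comparison had another probe set of the gene past the limma threshold in the other direction.

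Alternatives covered quantile normalization, the filter, the floor (5th percentile), the prior variance, 1 probe set per gene, blocks for sample number, scan day and period, a minimum fold of 1.5, the arrays of single periods, the identical columns, the low-correlation arrays, array weights and each of the 32 arrays that share a group with another left out in turn. Overlap of the mutants was set against 100 simulations with shared controls and against controls split by sample number. In 100 splits of the arrays (seed 1) the labels of 2 strains were exchanged. On simulated data with 200 changed probe sets, the averaged contrast found 35.8%, 85.1% and 100% of changes of 1.5, 2 and 4 fold, and called 7 unchanged probe sets. For the diaphragm 19.4% and 74.2% of the changes of 2 and 4 fold were found, and for the diaphragm against the limb muscles 10.4% and 65.2%. The list test found 1 of 1 shifted list. A second list of liver genes and a list of clock genes were written after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.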

Results

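Gene expression was measured on Affymetrix MG_U74Av2 arrays in 6 skeletal muscles of C57BL10 mice and of mdx and mdx5cv mice, 2 strains that each carry a mutation in Dmd, the gene of dystrophin, which links the cytoskeleton of the muscle fibre to the surrounding matrix. The muscles were the diaphragm, the EDL (extensor digitorum longus), the gastroc (gastrocnemius), the quadriceps, the soleus and the TA (tibialis anterior). Each of the 18 groups of strain and muscle had 2 samples, and each sample was RNA pooled from 5 male mice aged 8 weeks. The labels do not say whether samples 1 and 2 of a group come from separate pools, or whether muscles share mice. The p-values thus measure only the spread between these samples. Of the 36 columns, mdx gastroc sample 2 was identical to mdx quadriceps sample 2, and mdx5cv gastroc sample 1 to mdx5cv quadriceps sample 1. The quadriceps copies were kept, which left 34 arrays and 1 array each for mdx gastroc and mdx5cv gastroc. The median signal of the arrays ranged from 458 to 1026, and the number of arrays limits the precision of every value.

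C57BL10 TA sample 2 and mdx5cv quadriceps sample 2 stood apart. Their median Spearman correlation across genes with the others was 0.621 and 0.769 (rest 0.835 to 0.934). Their first percentile signals were 217.7 and 142.3 (rest 6 to 29.5). The ratio of the 3' to the 5' probe set of actin, a sign of RNA integrity, was 0.768 ± 0.114 in C57BL10 (SD, n = 12), 1.10 ± 0.343 in mdx (SD, n = 11) and 1.03 ± 0.126 in mdx5cv (SD, n = 11). That of Gapdh was 1.04 ± 0.270, 1.34 ± 0.894 and 1.10 ± 0.355 in the same order. Transcripts of liver-secreted proteins were abundant in the diaphragm arrays, where the 12 measured liver genes averaged 14.79 (log2 signal) in C57BL10, 14.92 in mdx and 13.41 in mdx5cv, against 7.65 in C57BL10 EDL. The TA held intermediate levels, 10.99 in C57BL10, 9.04 in mdx and 8.46 in mdx5cv. In quadriceps mdx sample 1 was at 9.48 and mdx5cv sample 2 at 9.59, and the other 4 arrays lay from 7.57 to 7.94. The 30 arrays with an experiment file fell into 4 scanning periods, of which the first held 5 C57BL10 arrays and no mutant, the second 5 mdx and 4 mdx5cv arrays, the third 4 C57BL10, 5 mdx and 6 mdx5cv arrays, and the fourth 1 C57BL10 array. Values with the period as a block use these arrays, and values within the third period use its 15 arrays.

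Dmd, the mutated gene, was measured in every sample. Its signal ranged from 369 to 1928 over the 12 C57BL10 arrays (median 668), from 104 to 586 over the 11 mdx arrays (median 216, 1 array at the floor) and from 158 to 519 over the 11 mdx5cv arrays (median 302). Averaged over the muscles Dmd fell in mdx (-1.50 ± 0.25 log2, limma adjusted p = 1.4e-04) and in mdx5cv (-1.25 ± 0.25, adjusted p = 0.0011). With the scanning period as a block these values were -1.36 (adjusted p = 0.023) and -1.26 (adjusted p = 0.026), and within the third period -1.21 (adjusted p = 0.21) and -0.95 (adjusted p = 0.26). Both mutations are point changes that the probes need not cover, and the ranges of the strains overlap, so the Dmd signal does not check the labels. Utrn, the gene of utrophin, the homologue of dystrophin, had values of 0.20 ± 0.22 in mdx (adjusted p = 0.56) and 0.27 ± 0.22 in mdx5cv (adjusted p = 0.50). In all comparisons that follow, gene values are log2 differences ± the limma standard error, adjusted p-values of gene lists come from camera, and a gene or list named as changed passed an adjusted p of 0.05 and did so with any 1 array left out, except where a p without an array is given. A gene with arrays of its lower group at the floor, such as Ccl2 (7 of the 12 C57BL10 arrays), Myh3 (6), Ccl8 (5) or Mmp12 (3), has a value that depends on the floor, and its place in the order of genes is open.

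**Figure D1:**
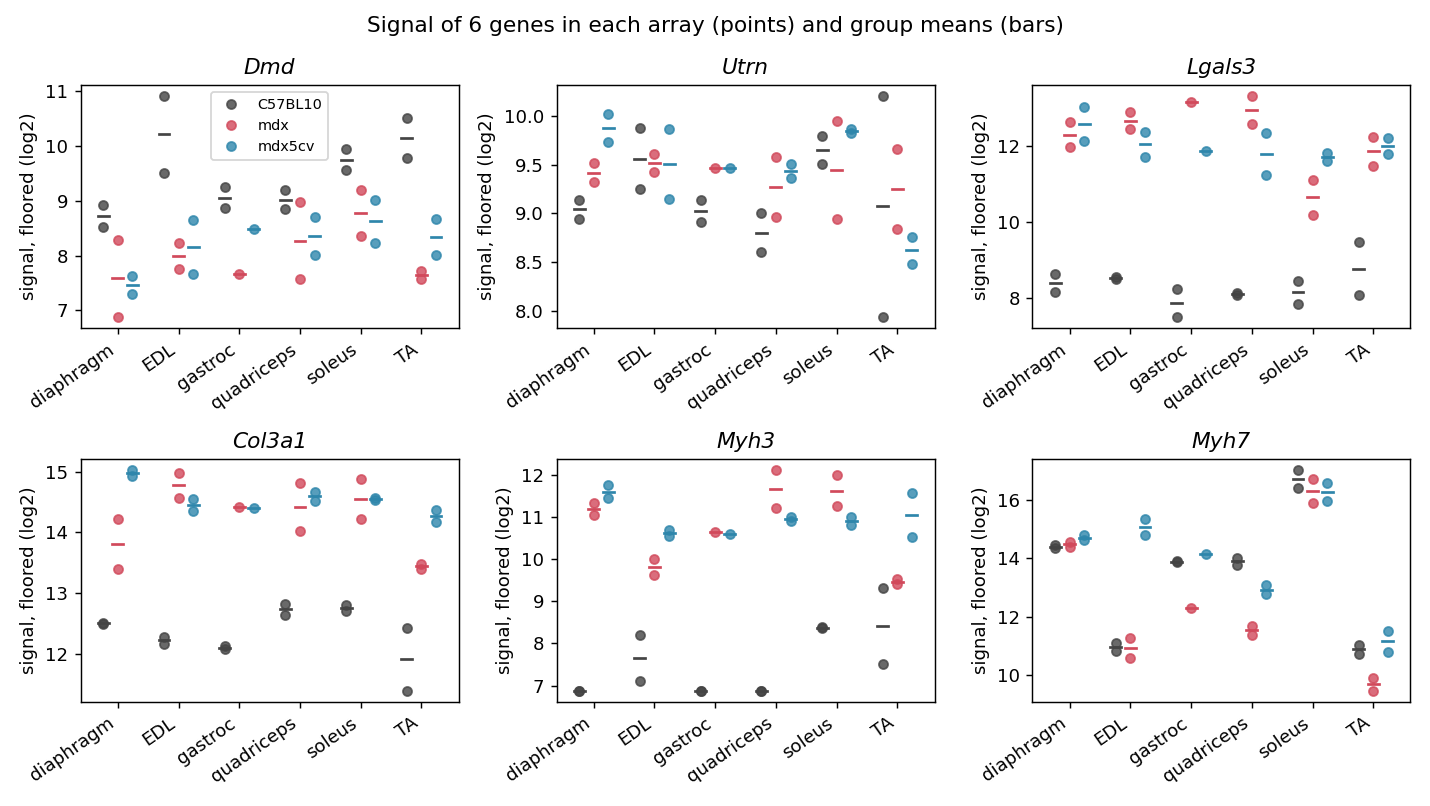
Signal (log2, floored) of Dmd, Utrn, Lgals3, Col3a1, Myh3 and Myh7 in each array by muscle and strain, with points for arrays and bars for group means. Lgals3 was 3.96 higher in mdx and 3.70 higher in mdx5cv than in C57BL10 as a mean over the muscles.

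On average over the 6 muscles, mdx was compared with C57BL10 (12 C57BL10 and 11 mdx arrays). Among the highest values were those of Lgals3, the gene of galectin-3, which macrophages make (3.96 ± 0.20), the embryonic myosin genes Myl4 (3.46 ± 0.18) and Myh3 (3.22 ± 0.20), the monocyte attractant Ccl2 (3.39 ± 0.25), the macrophage elastase Mmp12 (3.21 ± 0.26) and the lysosomal protease Ctss (3.09 ± 0.13). The lowest were Erdr1 (-3.09 ± 0.19), Pttg1 (-2.88 ± 0.21) and Ces1d (-1.72 ± 0.21), the slow myosin light chain Myl3 (-1.69 ± 0.21), Spg21 (-1.56 ± 0.21) and Ppp1r3c (-1.54 ± 0.19), which targets a phosphatase to glycogen. Of these Erdr1, Pttg1 and Spg21 fell largely in mdx alone. In total 1182 of 7453 probe sets passed the threshold, 748 higher and 434 lower.

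Among the 23 macrophage and monocyte markers, 20 rose and 3 did not pass (22 rose adjusted over the list alone, adjusted p = 2.0e-28, or 3.8e-05 with an estimated correlation). Besides Lgals3 they included Cd53 (2.71 ± 0.26) and Mpeg1 (2.55 ± 0.14) and the signalling adaptor Tyrobp (2.24 ± 0.18). Among the 25 lysosomal enzymes and cathepsins, 17 rose and 8 did not pass (17 rose and 1 fell adjusted over the list alone, adjusted p = 9.8e-11, or 4.2e-04 with an estimated correlation). Among these were Lgmn (1.68 ± 0.14), Ctsz (1.33 ± 0.17) and Ctsh (1.20 ± 0.13). Among the 17 antigen presentation genes, 10 rose and 7 did not pass (10 rose adjusted over the list alone, adjusted p = 5.4e-06, or 0.0091 with an estimated correlation and 0.051 without C57BL10 TA sample 1), including the MHC class II genes H2-Aa (1.98 ± 0.14) and H2-Ab1 (1.54 ± 0.17) and the invariant chain Cd74 (1.86 ± 0.21). Among the 12 interferon-stimulated genes, 5 rose and 7 did not pass (6 rose adjusted over the list alone, adjusted p = 0.0025, or 0.038 with an estimated correlation and 0.077 without mdx quadriceps sample 1), with Ifi204 (0.96 ± 0.17) and Irf8 (0.94 ± 0.17) highest. Among the 31 matrix genes, 21 rose and 10 did not pass (24 rose adjusted over the list alone, adjusted p = 4.7e-21, or 1.5e-05 with an estimated correlation). Periostin, Postn (3.08 ± 0.13), led, with the collagens Col5a2 (1.90 ± 0.14), Col6a3 (1.87 ± 0.12) and Col3a1 (1.87 ± 0.14). Among the 13 matrix proteases and inhibitors, 7 rose and 6 did not pass (7 rose and 1 fell adjusted over the list alone, adjusted p = 1.4e-05, or 0.0012 with an estimated correlation), such as Mmp3 (1.63 ± 0.27), Ctsk (1.49 ± 0.13) and Timp1 (1.36 ± 0.14). Among the 12 fibroblast markers, 8 rose and 4 did not pass (8 rose adjusted over the list alone, adjusted p = 1.9e-06, or 0.0049 with an estimated correlation), with S100a4 (2.00 ± 0.14) and Col1a1 (1.52 ± 0.15) highest. Among the 28 embryonic and regenerating muscle genes, 17 rose and 11 did not pass (18 rose adjusted over the list alone, adjusted p = 3.6e-17, or 1.1e-06 with an estimated correlation). They included the perinatal myosin Myh8 (2.61 ± 0.22) and Ankrd1 (2.53 ± 0.17), a titin-binding protein. These 8 lists held with an estimated correlation.

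Other lists passed in mdx only with the preset correlation. Of the 11 chemokines, 5 rose, 1 fell and 5 did not pass (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.0044, adjusted p = 0.057 with an estimated correlation), with Ccl8 (2.83 ± 0.27), Ccl7 (2.27 ± 0.27) and Ccl9 (1.58 ± 0.16) besides Ccl2. Of the 20 cell cycle genes, 6 rose and 14 did not pass (7 rose adjusted over the list alone, adjusted p = 0.0071, 0.062 without C57BL10 TA sample 1, adjusted p = 0.22 with an estimated correlation), among them Mad2l1 (0.97 ± 0.22) and Rrm2 (0.95 ± 0.24). Of the 13 slow fibre proteins, 1 rose, 5 fell and 7 did not pass (2 rose and 6 fell adjusted over the list alone, adjusted p = 0.038, 0.10 without mdx soleus sample 1, adjusted p = 0.54 with an estimated correlation). Here Myl2 (-1.44 ± 0.22) and Myh7 (-0.92 ± 0.14) fell and Tnni1 (0.86 ± 0.14) rose. Of the 21 fatty acid oxidation genes, 2 rose, 6 fell and 13 did not pass (2 rose and 9 fell adjusted over the list alone, adjusted p = 0.0037, adjusted p = 0.41 with an estimated correlation). Lipoprotein lipase, Lpl (-1.02 ± 0.20), fell and the pyruvate dehydrogenase kinase Pdk4 (1.06 ± 0.22) rose. Of the 43 oxidative phosphorylation genes, 1 rose, 3 fell and 39 did not pass (1 rose and 3 fell adjusted over the list alone, adjusted p = 0.035, 0.26 without mdx TA sample 1, adjusted p = 0.70 with an estimated correlation). Of the 11 adipocyte markers, 2 fell and 9 did not pass (3 fell adjusted over the list alone, adjusted p = 0.035, 0.093 without mdx diaphragm sample 1, adjusted p = 0.18 with an estimated correlation), Fasn (-0.67 ± 0.12) among them. Of the 6 erythroid markers, a measure of blood in the samples, 2 fell and 4 did not pass (4 fell adjusted over the list alone, adjusted p = 0.027, 0.055 without mdx quadriceps sample 1, adjusted p = 0.057 with an estimated correlation), with Alas2 (-0.83 ± 0.19) lowest. The other 18 lists had adjusted p-values of 0.055 (immediate early and dissection stress genes) to 0.98 (glycolysis and glycogen). They include the lymphocyte list (median -0.25, adjusted p = 0.20, adjusted p = 0.61 with an estimated correlation), of which Ms4a1 (-0.60 ± 0.18, adjusted p = 0.061 without C57BL10 gastroc sample 1) fell, and that of neutrophils, eosinophils and mast cells (-0.30, adjusted p = 0.33, adjusted p = 0.61 with an estimated correlation). The median of the TGF-beta and growth factor list (-0.08) differed in sign from its mean (0.09). Of the dystrophin-associated proteins, Dmd fell and Cav3 (0.58 ± 0.13) and Itga7 (0.43 ± 0.11) rose.

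With the scanning period as a block, 828 probe sets passed in the comparison of mdx with C57BL10, and within the third period 186. Among the 97 named genes past the threshold, 75 passed with the block and 37 within the third period. The mean of the macrophage list was 1.55, 1.62 with the block and 1.60 within the third period. The same values were 0.97, 0.95 and 1.00 for the matrix list, 1.18, 1.17 and 1.04 for the regenerating muscle list, -0.34, -0.36 and -0.34 for the slow fibre list and -0.52, -0.64 and -0.51 for the erythroid list.

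**Figure D2:**
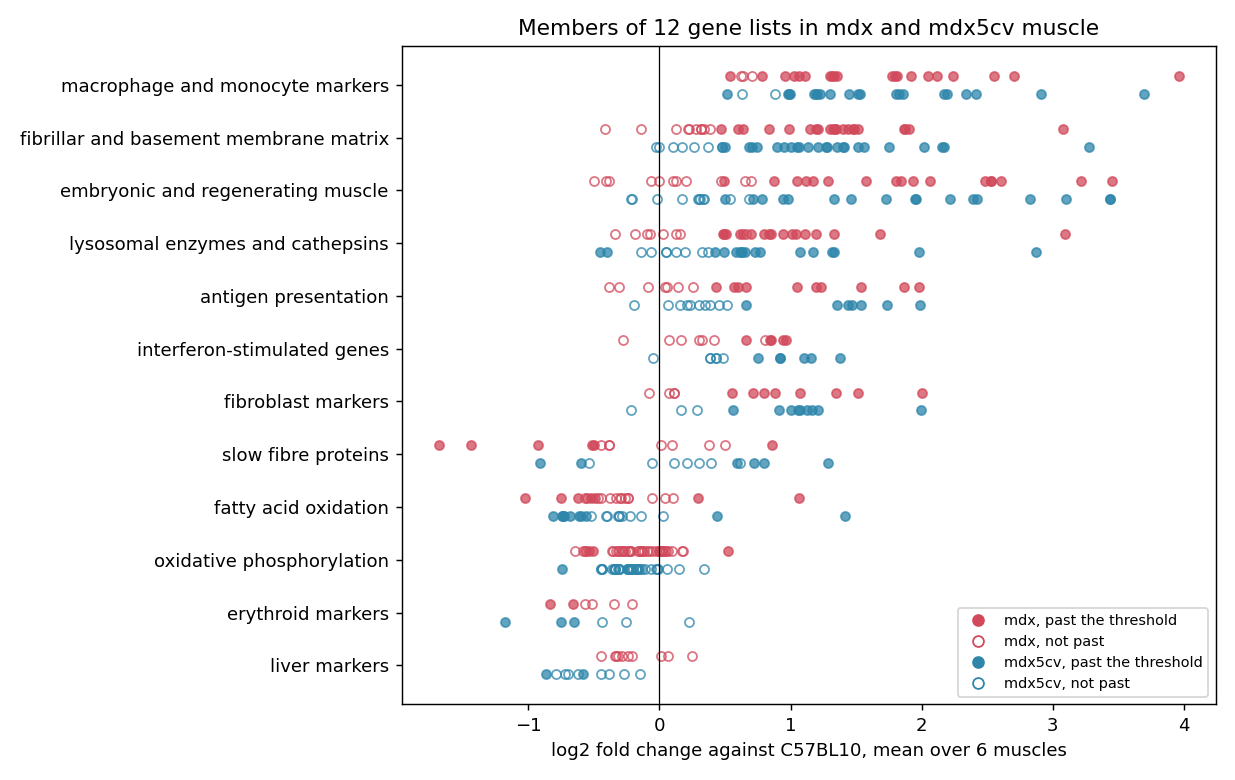
Log2 difference from C57BL10, as a mean over the muscles, of the members of 12 gene lists in mdx (red) and mdx5cv (blue), with a point for each gene, filled where it passed the threshold. The median of the macrophage and monocyte markers was 1.33 in mdx and 1.45 in mdx5cv.

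The second mutant, mdx5cv, was compared with C57BL10 in the same way (12 C57BL10 and 11 mdx5cv arrays). Among the highest genes were Ccl2 (3.71 ± 0.25), Lgals3 (3.70 ± 0.20), Myh3 (3.44 ± 0.20), Myl4 (3.44 ± 0.18), Postn (3.27 ± 0.13) and Mmp12 (3.13 ± 0.26). The lowest were Ces1d (-2.23 ± 0.21) and Inmt (-2.07 ± 0.14), the clock gene Per2 (-1.84 ± 0.19), the fatty acid transporter Slc27a1 (-1.67 ± 0.27), Rhou (-1.55 ± 0.17) and Gstt2 (-1.39 ± 0.33). Of 7453 probe sets 1112 passed, 779 higher and 333 lower.

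Of the 23 macrophage and monocyte markers, 21 rose and 2 did not pass (23 rose adjusted over the list alone, adjusted p = 3.5e-29, or 3.2e-05 with an estimated correlation). Besides Lgals3 came Cd53 (2.91 ± 0.26), Mpeg1 (2.41 ± 0.14) and Ccr2 (2.34 ± 0.18). Of the 31 matrix genes, 24 rose and 7 did not pass (25 rose adjusted over the list alone, adjusted p = 9.2e-23, or 9.0e-06 with an estimated correlation). Next to Postn stood Col3a1 (2.17 ± 0.14), Col5a2 (2.15 ± 0.14) and Vcan (2.02 ± 0.26). Of the 13 matrix proteases and inhibitors, 7 rose, 1 fell and 5 did not pass (7 rose and 1 fell adjusted over the list alone, adjusted p = 2.5e-05, or 0.0021 with an estimated correlation), among them Mmp3 (1.86 ± 0.27) and Timp1 (1.39 ± 0.14). Of the 28 embryonic and regenerating muscle genes, 17 rose and 11 did not pass (20 rose adjusted over the list alone, adjusted p = 2.6e-18, or 7.2e-07 with an estimated correlation). Of the 25 lysosomal genes, 15 rose, 2 fell and 8 did not pass (15 rose and 2 fell adjusted over the list alone, adjusted p = 6.0e-07, or 0.0030 with an estimated correlation), with Ctss (2.87 ± 0.13) and Lgmn (1.98 ± 0.14) highest. Of the 12 fibroblast markers, 9 rose and 3 did not pass (9 rose adjusted over the list alone, adjusted p = 1.3e-07, or 0.0024 with an estimated correlation), with S100a4 (2.00 ± 0.14) highest. Of the 17 antigen presentation genes, 7 rose and 10 did not pass (10 rose adjusted over the list alone, adjusted p = 2.2e-06, or 0.0069 with an estimated correlation), led by H2-Aa (1.98 ± 0.14) and H2-Ab1 (1.74 ± 0.17). Of the 12 interferon-stimulated genes, 6 rose and 6 did not pass (11 rose adjusted over the list alone, adjusted p = 5.2e-05, or 0.0072 with an estimated correlation), led by Isg15 (1.37 ± 0.28). Of the 6 erythroid markers, a measure of blood, 3 fell and 3 did not pass (3 fell adjusted over the list alone, adjusted p = 0.0050, or 0.025 with an estimated correlation), with Alas2 (-1.18 ± 0.19) and Hba-a1 (-0.75 ± 0.19). These 9 lists held with an estimated correlation.

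Other lists passed in mdx5cv with the preset correlation alone. Among the 11 chemokines, 4 rose, 2 fell and 5 did not pass (5 rose and 2 fell adjusted over the list alone, adjusted p = 0.0038, adjusted p = 0.059 with an estimated correlation). Among the 9 complement genes, 3 rose and 6 did not pass (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.046, 0.14 without C57BL10 TA sample 1, adjusted p = 0.20 with an estimated correlation). Among the 20 cell cycle genes, 8 rose and 12 did not pass (10 rose adjusted over the list alone, adjusted p = 0.0015, adjusted p = 0.15 with an estimated correlation), among them Ccna2 (1.28 ± 0.27) and Ccnb2 (0.93 ± 0.19). Among the 21 fatty acid oxidation genes, 2 rose, 9 fell and 10 did not pass (2 rose and 12 fell adjusted over the list alone, adjusted p = 1.7e-05, adjusted p = 0.20 with an estimated correlation), with Lpl (-0.81 ± 0.20) and Acadm (-0.74 ± 0.19) down and Pdk4 (1.42 ± 0.22) up. Among the 19 glycolysis and glycogen genes, 4 fell and 15 did not pass (6 fell adjusted over the list alone, adjusted p = 1.7e-04, adjusted p = 0.29 with an estimated correlation), with the hexokinase Hk2 (-0.86 ± 0.15) and the glucose transporter Slc2a4 (-0.84 ± 0.19) down. Among the 43 oxidative phosphorylation genes, 1 fell and 42 did not pass (1 fell adjusted over the list alone, adjusted p = 8.7e-05, adjusted p = 0.56 with an estimated correlation), the member being Cox7b (-0.74 ± 0.20). Among the 11 adipocyte markers, 3 fell and 8 did not pass (4 fell adjusted over the list alone, adjusted p = 0.0025, adjusted p = 0.056 with an estimated correlation), with Scd1 (-0.71 ± 0.19) and Fasn (-0.50 ± 0.12). Among the 10 liver markers, 2 fell and 8 did not pass (3 fell adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.29 with an estimated correlation), namely Cyp2e1 (-0.58 ± 0.14) and Tat (-0.87 ± 0.26, adjusted p = 0.056 without mdx5cv TA sample 1). Of the slow fibre genes Tnni1 (1.28 ± 0.14), Tnnt1 (0.80 ± 0.19) and Atp2a2 (0.72 ± 0.13) rose and Mb (-0.91 ± 0.17) fell. Without the EDL the values were 0.73 (adjusted p = 0.0018), 0.24 (adjusted p = 0.53) and 0.04 (adjusted p = 0.91), so the rise of Tnnt1 and Atp2a2 came largely from the EDL. The list did not pass (adjusted p = 0.29, adjusted p = 0.92 with an estimated correlation). The remaining 15 lists did not pass either, with adjusted p-values of 0.24 to 0.95. Signs differed between median, mean and test for the lymphocyte (0.10, 0.07, down), smooth muscle (-0.14, 0.04, down), nerve (0.07, 0.01, down) and homeobox lists (0.04, 0.02, down).

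With the scanning period as a block 814 probe sets passed in mdx5cv, and within the third period 271. Of 99 named genes past the threshold, 83 passed with the block and 51 within the third period, where Tat turned (0.22). List means were 1.60, 1.70 with the block and 1.81 within the third period for the macrophage list, 1.06, 1.05 and 1.05 for the matrix list, 1.24, 1.21 and 1.10 for the regenerating muscle list and -0.51, -0.62 and -0.42 for the erythroid list. The liver list turned from -0.55 and -0.43 to 0.30 within the third period.

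The same genes moved in both mutants to a large part. Of the probe sets past the threshold, 578 were higher in both and 173 lower in both (290 without C57BL10 TA sample 2), and 5 went opposite ways. Lgals3, Ccl2, Myh3, Myl4 and Mmp12 were among the 6 highest in each mutant, and Ces1d was among the 6 lowest in each. Independent lists of these sizes would share 78.2 and 19.4. The log2 differences correlated across genes, which are not independent replicates, with r = 0.825 and a covariance of 0.177. Both comparisons use the same C57BL10 arrays, and 100 simulations of unchanged groups against those arrays gave r = 0.463 and a covariance of 0.0203, which leaves a covariance of 0.157. With mdx set against C57BL10 samples 1 and mdx5cv against samples 2, 365 probe sets were shared higher and 58 lower (35.6 and 3.03 for independent lists, r = 0.764, covariance 0.170). The opposite split gave 356 and 55 (44.8 and 4.54, r = 0.604, covariance 0.148).

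Set against each other, the mutants differed in few genes (11 arrays each). Higher in mdx5cv were Spg21 (2.89 ± 0.22), Erdr1 (2.87 ± 0.20) and Pttg1 (2.32 ± 0.22), the chromatin protein Rbbp4 (1.74 ± 0.14), the glycine cleavage protein Gcsh (1.40 ± 0.12) and the core clock gene Arntl (1.13 ± 0.16). Lower were the clock-controlled transcription factor Dbp (-1.41 ± 0.19), the clock gene Per2 (-1.41 ± 0.20), Mid1ip1 (-0.96 ± 0.17) and Inmt (-0.81 ± 0.15), Tef (-0.79 ± 0.18, adjusted p = 0.12 without mdx5cv EDL sample 2) and the RNA-binding protein Nono (-0.77 ± 0.13). Erdr1 had a signal of 248 to 1401 in the 11 mdx arrays and of 4113 to 9923 in the other 23 arrays. Its probe set, like those of Spg21 and Myh7, is of a kind that can detect related transcripts. In mdx EDL sample 1, described as mdx5cv, Erdr1 was at 942, among the mdx values, a check chosen after its values were seen. In all 39 of 7453 probe sets passed, 26 higher and 13 lower in mdx5cv, and 62 without mdx quadriceps sample 1. Dmd (0.25 ± 0.26, adjusted p = 0.75) and Utrn (0.06 ± 0.23, adjusted p = 0.95) did not pass.

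Some slow fibre genes were higher in mdx5cv. Among the 13 slow fibre genes, 5 rose and 8 did not pass (8 rose and 1 fell adjusted over the list alone, adjusted p = 2.9e-08, adjusted p = 0.15 with an estimated correlation). The members were led by the slow myosin heavy chain Myh7 (1.51 ± 0.15), the slow light chains Myl2 (1.38 ± 0.23) and Myl3 (1.15 ± 0.22) and the slow calcium pump Atp2a2 (0.71 ± 0.14). Tpm3 (0.71 ± 0.15, adjusted p = 0.056 without mdx5cv soleus sample 2) followed. The mean of this list was 0.57 over the muscles, 0.46 with the period as a block, 0.71 within the second period and 0.30 within the third. Without the EDL the values were 0.98 (adjusted p = 0.0030) for Myh7, 0.91 (adjusted p = 0.18) for Myl2, 0.40 (adjusted p = 0.55) for Myl3, 0.38 (adjusted p = 0.37) for Atp2a2 and 0.28 (adjusted p = 0.54) for Tpm3. The list mean came largely from the EDL, where it was 2.09, against 0.68 in TA, 0.55 in gastroc, 0.08 in diaphragm, 0.02 in soleus and -0.01 in quadriceps. Among lists lower in mdx5cv, glycolysis and glycogen had a median of -0.38 (adjusted p = 1.3e-09, adjusted p = 0.15 with an estimated correlation). Fast fibre proteins had -0.34 (adjusted p = 3.2e-04, adjusted p = 0.53 with an estimated correlation) and liver markers -0.39 (adjusted p = 0.0017, 0.11 without mdx5cv quadriceps sample 1, adjusted p = 0.50 with an estimated correlation). Also lower, with the preset correlation alone, were immediate early and dissection stress genes (-0.07, adjusted p = 0.0022, adjusted p = 0.14 with an estimated correlation). The lysosomal list (-0.11, adjusted p = 0.0074, adjusted p = 0.15 with an estimated correlation) had a mean of -0.09, -0.06 with the period as a block, and 0.03 and -0.04 within the second and the third period. The tendon and cartilage list was higher (0.51, adjusted p = 0.040, 0.11 without mdx5cv quadriceps sample 1, adjusted p = 0.15 with an estimated correlation). Median, mean and test differed in sign for the macrophage (-0.01, 0.05, down), matrix protease (0.03, 0.03, down), erythroid (-0.02, 0.01, down) and heat shock lists (0.05, 0.00, down). The B cell marker Ms4a1 (0.87 ± 0.19, adjusted p = 0.071 without mdx5cv EDL sample 2) was higher. With the period as a block 81 probe sets passed, within the second period 6 and within the third 10. The 18 named genes past the threshold all passed with the block, and 6 within the third period. The glycolysis mean was -0.34, -0.42 with the block, -0.22 and -0.60 within the second and the third period, and the liver mean -0.37, -0.34, -0.93 and -0.09.

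**Figure D3:**
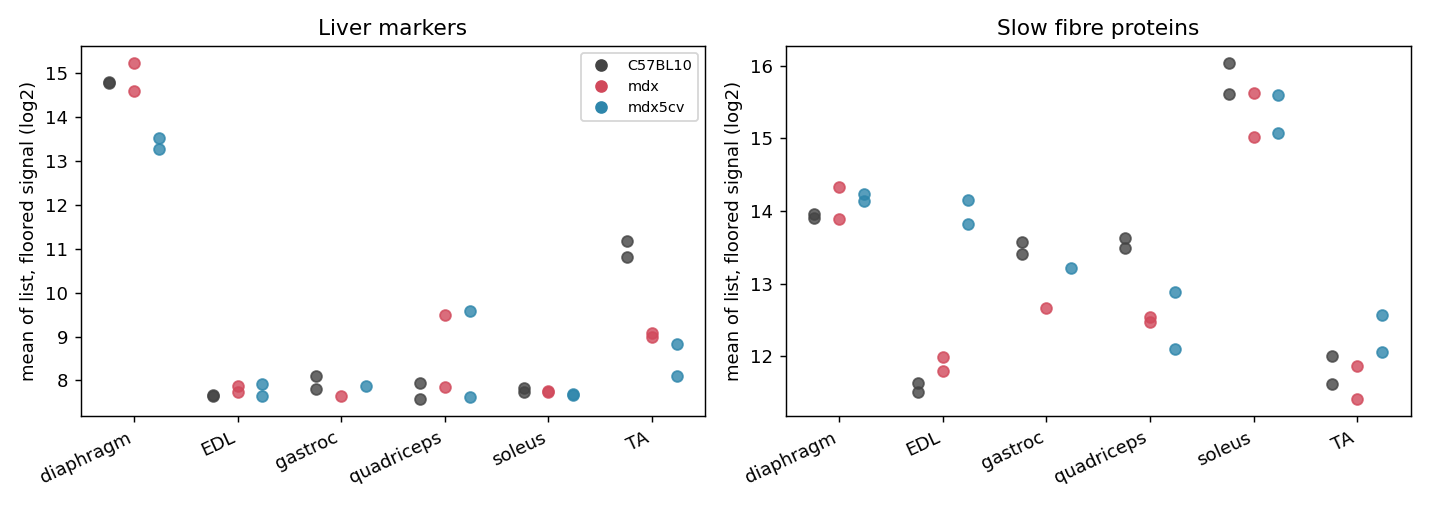
Mean signal (log2, floored) of the liver list and of the slow fibre list in each array by muscle, with points for arrays coloured by strain. The liver list averaged 14.79 in C57BL10 diaphragm and 10.99 in C57BL10 TA, against 7.78 in C57BL10 soleus.

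In each muscle, mdx and mdx5cv arrays together were set against the 2 C57BL10 arrays to ask where the lack of dystrophin acts. Where the values of the mutants lie more than 1.5 apart, both are given. In the diaphragm (4 mutant arrays) the embryonic and perinatal myosins Myl4 (5.41 ± 0.36), Myh3 (4.51 ± 0.40) and Myh8 (4.30 ± 0.44) rose, with the matrix genes Postn (4.08 ± 0.27) and Tnc (3.08 ± 0.35) and the growth factor Igf2 (3.40 ± 0.39). Among the lowest were Cyp4a12b (-2.20 ± 0.48, adjusted p = 0.13 without C57BL10 diaphragm sample 2), Upp2 (-1.93 ± 0.47, -0.38 in mdx and -3.49 in mdx5cv, adjusted p = 0.23 without C57BL10 diaphragm sample 2) and Erdr1 (-1.72 ± 0.39, -2.88 in mdx and -0.55 in mdx5cv, adjusted p = 0.16 without C57BL10 diaphragm sample 2). Among the 28 regenerating muscle genes, 15 rose and 13 did not pass (21 rose adjusted over the list alone, adjusted p = 3.7e-31, or 1.2e-08 with an estimated correlation). Among the 31 matrix genes, 13 rose and 18 did not pass (20 rose adjusted over the list alone, adjusted p = 1.5e-20, or 1.8e-05 with an estimated correlation). Among the 23 macrophage markers, 9 rose and 14 did not pass (16 rose adjusted over the list alone, adjusted p = 6.0e-18, or 6.4e-04 with an estimated correlation), with Lgals3 (4.05 ± 0.41) and Mpeg1 (2.46 ± 0.28). The liver list had a median of -0.56 (adjusted p = 0.011, 0.15 without mdx diaphragm sample 1, adjusted p = 0.43 with an estimated correlation) and Dmd a value of -1.20 ± 0.52 (adjusted p = 0.29). In all 222 probe sets passed, 171 higher and 51 lower. With the period as a block 62 probe sets passed, as did 76 without C57BL10 diaphragm sample 1 and 73 without C57BL10 diaphragm sample 2.

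In the EDL (4 mutant arrays) Ccl2 (4.20 ± 0.50), Mmp12 (3.88 ± 0.53), Lgals3 (3.83 ± 0.41) and Ccl8 (3.70 ± 0.55) rose. Of the 13 slow fibre genes, 8 rose and 5 did not pass (8 rose adjusted over the list alone, adjusted p = 2.1e-11, or 0.024 with an estimated correlation). Atp2a2 (2.94 ± 0.27, 1.77 in mdx and 4.12 in mdx5cv) and Tnni1 (2.94 ± 0.28, 1.80 in mdx and 4.07 in mdx5cv) rose, and the list mean was 2.09 higher in mdx5cv EDL than in mdx EDL. Of the 23 macrophage markers, 13 rose and 10 did not pass (20 rose adjusted over the list alone, adjusted p = 3.6e-32, or 2.6e-05 with an estimated correlation). Of the 31 matrix genes 7 rose and 24 did not pass (16 rose adjusted over the list alone, adjusted p = 1.6e-16, or 4.8e-05 with an estimated correlation). Among the lowest were Slc27a1 (-2.61 ± 0.55, -4.31 in mdx and -0.91 in mdx5cv, adjusted p = 0.17 without C57BL10 EDL sample 1), Ces1d (-2.49 ± 0.43), Dmd (-2.13 ± 0.52, adjusted p = 0.45 without C57BL10 EDL sample 2) and the methyltransferase Inmt (-2.02 ± 0.29). In the EDL 193 probe sets passed, 169 higher and 24 lower. As a block, the period gave 254 probe sets; there were 88 without C57BL10 EDL sample 1.

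In the gastroc there was 1 mdx and 1 mdx5cv array, each taken to vary like the other groups and never left out. High values were those of Lgals3 (4.64 ± 0.47), Ccl2 (4.31 ± 0.58), Cd53 (4.06 ± 0.61) and Lilr4b (4.03 ± 0.45), all of immune cells or their attraction. Among the 23 macrophage markers, 15 rose and 8 did not pass (21 rose adjusted over the list alone, adjusted p = 7.5e-38, or 9.1e-06 with an estimated correlation). Among the 28 regenerating muscle genes, 12 rose and 16 did not pass (14 rose adjusted over the list alone, adjusted p = 5.5e-16, or 1.9e-06 with an estimated correlation), with Myh3 (3.73 ± 0.47) and Ankrd1 (3.62 ± 0.40). Among the lowest genes were Ces1d (-2.48 ± 0.49, adjusted p = 0.083 without C57BL10 gastroc sample 1), Nup107 (-2.00 ± 0.46, -0.60 in mdx and -3.39 in mdx5cv, adjusted p = 0.12 without C57BL10 gastroc sample 1) and Inmt (-1.89 ± 0.33). The erythroid list was lower, with a median of -0.82 (adjusted p = 0.013, 0.17 without C57BL10 gastroc sample 1, or 0.039 with an estimated correlation and 0.30 without C57BL10 gastroc sample 1), and Dmd had a value of -0.98 ± 0.60 (adjusted p = 0.70). In the gastroc 168 probe sets passed, 160 higher and 8 lower, 377 with the gastroc in place of the quadriceps copies and 346 over all 36 columns. A period block gave 214, and 74 without C57BL10 gastroc sample 1 and 100 without C57BL10 gastroc sample 2 passed.

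In the quadriceps (4 mutant arrays) high values were those of Myh3 (4.43 ± 0.40), Ccl2 (4.39 ± 0.50), Lgals3 (4.26 ± 0.41) and Mmp12 (4.17 ± 0.53). Of the 23 macrophage markers, 20 rose and 3 did not pass (22 rose adjusted over the list alone, adjusted p = 4.8e-32, or 1.8e-05 with an estimated correlation). Of the 31 matrix genes 18 rose and 13 did not pass (22 rose adjusted over the list alone, adjusted p = 7.1e-20, or 1.8e-05 with an estimated correlation). Among the lowest were Ces1d (-2.61 ± 0.43), Myl3 (-2.56 ± 0.43) and Erdr1 (-2.18 ± 0.39, -4.07 in mdx and -0.29 in mdx5cv). The liver list had a median of 1.14 (adjusted p = 0.017, 0.38 without mdx5cv quadriceps sample 2, adjusted p = 0.49 with an estimated correlation). Dmd had a value of -0.71 ± 0.52 (adjusted p = 0.49). In the quadriceps 403 probe sets passed, 292 higher and 111 lower. The period block gave 620 probe sets. Without 1 quadriceps array 162 (C57BL10 sample 1), 163 (C57BL10 sample 2), 621 (mdx sample 1) and 733 (mdx5cv sample 1) passed. After quantile normalization the median of all probe sets moved from 0.01 to -0.12.

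In the soleus (4 mutant arrays) Ccl8 (3.67 ± 0.55), Myh8 (3.62 ± 0.44), C1qtnf3 (3.22 ± 0.50) and Myl4 (3.17 ± 0.36) rose. Among the 31 matrix genes, 11 rose and 20 did not pass (16 rose adjusted over the list alone, adjusted p = 1.0e-19, or 2.3e-05 with an estimated correlation), with the crosslinking enzyme Lox (2.08 ± 0.28) and Col3a1 (1.80 ± 0.29). Among the 23 macrophage markers, 11 rose and 12 did not pass (14 rose adjusted over the list alone, adjusted p = 1.8e-20, or 2.7e-04 with an estimated correlation). Among the 28 regenerating muscle genes 10 rose and 18 did not pass (13 rose adjusted over the list alone, adjusted p = 9.1e-17, or 1.4e-06 with an estimated correlation). Among the lowest were Pttg1 (-2.46 ± 0.43, -4.18 in mdx and -0.75 in mdx5cv, adjusted p = 0.057 without C57BL10 soleus sample 1) and Erdr1 (-1.85 ± 0.39, -3.14 in mdx and -0.57 in mdx5cv, adjusted p = 0.20 without C57BL10 soleus sample 1). The erythroid list was lower, with a median of -0.91 (adjusted p = 0.0021, or 0.016 with an estimated correlation), and Dmd had a value of -1.05 ± 0.52 (adjusted p = 0.54). In the soleus 117 probe sets passed, 103 higher and 14 lower. With the period as a block 120 probe sets passed, as did 38 without C57BL10 soleus sample 1 and 44 without C57BL10 soleus sample 2.

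In the TA (4 mutant arrays) Tmsb10 (3.20 ± 0.41), Lgals3 (3.16 ± 0.41), Peg3 (2.99 ± 0.31) and Ctss (2.94 ± 0.26) rose. Of the 31 matrix genes, 11 rose and 20 did not pass (16 rose adjusted over the list alone, adjusted p = 2.3e-08, or 0.0033 with an estimated correlation and 0.16 without C57BL10 TA sample 1), and of the 25 lysosomal genes 8 rose and 17 did not pass (14 rose and 1 fell adjusted over the list alone, adjusted p = 3.0e-06, or 0.0084 with an estimated correlation and 0.24 without C57BL10 TA sample 1). Among the lowest were genes of liver, Ahsg (-3.65 ± 0.52), Cyp3a11 (-3.21 ± 0.49), Fabp1 (-3.20 ± 0.49) and Apoa1 (-3.12 ± 0.61, -2.18 in mdx and -4.07 in mdx5cv). Of the 10 liver markers 6 fell and 4 did not pass (10 fell adjusted over the list alone, adjusted p = 4.3e-10, or 0.047 with an estimated correlation and 0.28 without C57BL10 TA sample 1). Dmd (-2.16 ± 0.52, adjusted p = 0.27 without C57BL10 TA sample 2) and Myl3 (-2.64 ± 0.43) fell. In the TA 322 probe sets passed, 242 higher and 80 lower, but 246 higher and 269 lower without a filter on probe sets. Quantile normalization gave 874 and array weights 15. As a block, the period gave 116 probe sets; there were 2070 without C57BL10 TA sample 1, 123 without C57BL10 TA sample 2, 176 without mdx TA sample 2, 180 without mdx5cv TA sample 1 and 194 without mdx5cv TA sample 2. C57BL10 TA sample 2 stood apart, and after quantile normalization the median of all probe sets moved from 0.00 to 0.15.

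Across the 6 muscle comparisons 776 probe sets passed in at least 1 muscle (1255 without mdx5cv quadriceps sample 1 and 2602 without C57BL10 TA sample 1), and 26 were higher past the threshold in all 6 (16 without C57BL10 soleus sample 1 and 17 without C57BL10 soleus sample 2). The number past it in opposite directions in 2 muscles was 14 and ran from 4 without C57BL10 quadriceps sample 1 to 124 without C57BL10 TA sample 1. The 26 included Lgals3, Myl4, Myh3, Postn, Col3a1, Ctss, Mt2, Igf2 and S100a4. Lgals3 ranged from 3.03 (soleus) to 4.64 (gastroc), and Ctss from 2.32 (diaphragm) to 3.66 (quadriceps). The macrophage, matrix, matrix protease, regenerating muscle, lysosomal and fibroblast lists passed the test in each muscle. Leaving out C57BL10 TA sample 1 ended this in TA for the macrophage (adjusted p = 0.24), regenerating muscle (adjusted p = 0.061) and matrix protease lists (adjusted p = 0.28), and in EDL 5 arrays ended it for the fibroblast list, C57BL10 EDL sample 2 with the highest value (adjusted p = 0.37). Each held with an estimated correlation in all muscles except the fibroblast list in the EDL (adjusted p = 0.20), and in TA all 7 lists that held lost it without C57BL10 TA sample 1. It was also lost by the lysosomal list in diaphragm (0.057 without mdx diaphragm sample 2) and soleus (0.073 without C57BL10 soleus sample 2) and the matrix protease list in EDL (0.080 without C57BL10 EDL sample 1). The log2 differences of all probe sets correlated across genes, which are not independent replicates, with r from -0.02 (quadriceps and TA) to 0.60 (EDL and quadriceps).

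The change in the diaphragm was then tested against the mean change in the 5 limb muscles. The stress-response gene Gadd45b (2.45 ± 0.35) and the embryonic light chain Myl4 (2.35 ± 0.40, adjusted p = 0.24 without C57BL10 diaphragm sample 2) changed more upward in the diaphragm, as did Tnc (2.13 ± 0.39, adjusted p = 0.19 without C57BL10 diaphragm sample 1) and Comtd1 (2.77 ± 0.55, adjusted p = 0.52 without C57BL10 diaphragm sample 1). Pcbd1 (-3.12 ± 0.34), an enzyme of pterin recycling, changed more downward, with Cyp4v3 (-2.53 ± 0.36, adjusted p = 0.096 without C57BL10 diaphragm sample 2), Cpt1a (-1.98 ± 0.41, adjusted p = 0.52 without C57BL10 diaphragm sample 1), Csad (-1.82 ± 0.34, adjusted p = 0.22 without C57BL10 diaphragm sample 1) and Ccl9 (-1.78 ± 0.37, adjusted p = 0.52 without C57BL10 diaphragm sample 1). Of the 28 regenerating muscle genes, 1 rose and 27 did not pass (8 rose adjusted over the list alone, adjusted p = 7.7e-14, or 4.2e-06 with an estimated correlation). Pcbd1 was at the floor in 5 of the 12 C57BL10 arrays, so the size of its change depends on the floor. The part of liver transcripts, present in the C57BL10 diaphragm, was not tested. The liver list had a median of -0.30 here (adjusted p = 0.15, adjusted p = 0.82 with an estimated correlation). The other lists that passed had adjusted p-values of 0.29 or more with an estimated correlation. In all 17 of 7453 probe sets passed, 4 higher and 13 lower. The period block gave 3 probe sets. The number was 5 without C57BL10 diaphragm sample 1, 3 without sample 2 and 9 without mdx5cv diaphragm sample 2. It was 11 without any 1 mdx EDL or mdx5cv soleus sample, 28 without mdx5cv quadriceps sample 2 and 31 without C57BL10 TA sample 1. Without C57BL10 diaphragm sample 1 there were 3 higher and 2 lower. After quantile normalization the share of higher calls was 36.4% against 23.5%. Dmd (0.20 ± 0.57, adjusted p = 1.00) did not pass.

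A joint F test asked whether a gene's change differed between any of the 6 muscles, and 50 probe sets passed (limma). Genes of slow fibres and of liver were among them. The change of Atp2a2 ran from -0.87 in quadriceps to 2.94 in EDL (adjusted p = 1.8e-05), that of Tnni1 from -0.55 in soleus to 2.94 in EDL (adjusted p = 5.6e-04) and that of Myh7 from -1.67 in quadriceps to 2.03 in EDL (adjusted p = 5.6e-04). In EDL the values of Atp2a2, Tnni1 and Myh7 were 1.77, 1.80 and -0.05 in mdx and 4.12, 4.07 and 4.11 in mdx5cv. Of the liver genes, Ahsg ran from -3.65 in TA to 1.03 in quadriceps (adjusted p = 0.011) and Mup3 from -2.66 in TA to 1.81 in gastroc (adjusted p = 0.0098). Pcbd1 ran from -1.34 in diaphragm to 2.91 in gastroc (adjusted p = 9.5e-06). Postn rose in every muscle, least in soleus (1.61) and most in diaphragm (4.08, adjusted p = 0.0066). These 7 genes were chosen here after their values were seen. Each passed with any 1 of the 32 arrays that share a group with another left out. The block for period gave 26. There were 29 without C57BL10 diaphragm sample 1, 24 without C57BL10 diaphragm sample 2, 30 without mdx diaphragm sample 1, 28 without mdx5cv diaphragm sample 1, 31 without mdx5cv diaphragm sample 2, 89 without mdx5cv quadriceps sample 1, 30 without C57BL10 soleus sample 2 and 723 without C57BL10 TA sample 1.

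Among C57BL10 arrays, each muscle was set against the mean of the other 5 (2 arrays each) to describe the muscles without the mutation. In the diaphragm the highest transcripts were of liver-secreted proteins, Apoa1 (8.18 ± 0.54), Serpina1b (7.85 ± 0.62), Alb (7.81 ± 0.82) and Ahsg (7.47 ± 0.46). Of the 10 liver markers 10 were higher (10 were higher adjusted over the list alone, adjusted p = 2.4e-25, or 0.0046 with an estimated correlation). The growth factor binding protein Igfbp2 (4.18 ± 0.36), the mesothelial marker Upk3b (3.08 ± 0.49) and the MHC class I genes B2m (1.90 ± 0.32) and H2-K1 (1.77 ± 0.28) were higher. Of the 17 antigen presentation genes, 10 were higher and 7 did not pass (11 were higher adjusted over the list alone, adjusted p = 1.4e-07, or 0.0054 with an estimated correlation). Lower were the fast fibre genes Actn3 (-2.68 ± 0.34) and Myoz1 (-1.89 ± 0.28) and the calcium channel subunit Cacng1 (-2.58 ± 0.22). Of the 28 regenerating muscle genes 10 were lower and 18 did not pass (10 were lower adjusted over the list alone, adjusted p = 1.8e-04, or 0.0046 with an estimated correlation). In the C57BL10 diaphragm 1208 probe sets passed, 574 higher and 634 lower. The larger direction turned in 7 of 29 settings, as without a filter (738 higher and 542 lower), with a filter on the highest group mean (768 higher and 653 lower) or without sample 1 (343 higher and 195 lower) or sample 2 (332 higher and 218 lower). A period block gave 841, and 538 without C57BL10 diaphragm sample 1 and 550 without C57BL10 diaphragm sample 2 passed. After quantile normalization the median of all probe sets was -0.15 against -0.14.

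The soleus was the slow muscle of the set. The slow troponins Tnnc1 (4.68 ± 0.43), Tnni1 (4.18 ± 0.25) and Tnnt1 (3.94 ± 0.34) and the slow calcium pump Atp2a2 (4.11 ± 0.24) were higher. Among the 13 slow fibre proteins 10 were higher and 3 did not pass (13 were higher adjusted over the list alone, adjusted p = 1.5e-44, or 2.5e-04 with an estimated correlation). The heat shock genes Hspa1a (2.53 ± 0.35) and Hspa1b (2.02 ± 0.29) and the matrix gene Postn (2.07 ± 0.24) were higher. Lower were myostatin, Mstn (-2.78 ± 0.28), the fast fibre actinin Actn3 (-2.16 ± 0.34), and the liver transcript Plg (-3.02 ± 0.40). In the C57BL10 soleus 195 probe sets passed, 96 higher and 99 lower, and the larger direction turned in 12 of 30 settings. The period block gave 264 probe sets. Without 1 C57BL10 array 65 (soleus sample 1), 70 (soleus sample 2) and 317 (TA sample 1) passed.

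The EDL had the low slow fibre levels of a fast muscle. Of the 13 slow fibre proteins, 9 were lower and 4 did not pass (11 were lower adjusted over the list alone, adjusted p = 2.5e-35, or 9.9e-04 with an estimated correlation), with Myl3 (-4.14 ± 0.39) and Atp2a2 (-3.48 ± 0.24). Of the 11 adipocyte markers, 4 were lower and 7 did not pass (7 were lower adjusted over the list alone, adjusted p = 2.2e-09, or 0.0015 with an estimated correlation). Of the 10 liver markers 8 were lower and 2 did not pass (9 were lower adjusted over the list alone, adjusted p = 1.5e-19, or 0.0062 with an estimated correlation). Their mean was 7.65 in EDL and 7.75 to 7.95 in quadriceps, soleus and gastroc, against 14.79 in diaphragm and 10.99 in TA. Against the other 4 limb muscles the adjusted p was 8.3e-07, or 0.20 with an estimated correlation. The imprinted gene Peg3 (2.09 ± 0.28) and Apod (1.88 ± 0.21) were higher. The major urinary protein Mup3 (-3.95 ± 0.45) was lower. In the C57BL10 EDL 125 probe sets passed, 29 higher and 96 lower, and 28 against those 4 muscles. With the period as a block 143 probe sets passed. Without 1 C57BL10 array 46 (EDL sample 1), 51 (EDL sample 2) and 294 (TA sample 1) passed.

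For the gastroc and quadriceps of C57BL10, no gene named here passed with every array left out in turn. In the gastroc Mstn (1.84 ± 0.28, adjusted p = 0.15 without C57BL10 gastroc sample 1) was higher and Mup3 (-3.39 ± 0.45, adjusted p = 0.063 without C57BL10 gastroc sample 1) lower. Against the other 4 limb muscles Mup3 did not pass (adjusted p = 0.11). In the C57BL10 gastroc 65 probe sets passed, 19 higher and 46 lower, and 4 against those 4 muscles (3 higher and 1 lower). As a block, the period gave 80 probe sets. Without 1 C57BL10 array 5 (gastroc sample 1), 23 (gastroc sample 2) and 145 (TA sample 1) passed. In the quadriceps Ighm (1.49 ± 0.23, adjusted p = 0.090 without C57BL10 quadriceps sample 2) was higher. In the C57BL10 quadriceps 77 probe sets passed, 21 higher and 56 lower, and 5 against the other 4 limb muscles, all higher. A period block gave 96, and 205 passed without C57BL10 TA sample 1. Without 1 other C57BL10 array 47 (diaphragm sample 1), 50 (diaphragm sample 2), 16 (quadriceps sample 1) and 10 (quadriceps sample 2) passed. Of those without C57BL10 TA sample 1, 107 were higher. Quantile normalization moved the share of higher calls in the quadriceps from 27.3% to 44.4% and the median of all probe sets from -0.02 to 0.09.

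In the C57BL10 TA the liver transcripts Alb (4.88 ± 0.82), Serpina1b (3.89 ± 0.62) and Mup3 (3.41 ± 0.45) were higher. Of the 10 liver markers 6 were higher and 4 did not pass (8 were higher and 1 was lower adjusted over the list alone, adjusted p = 1.5e-05, adjusted p = 0.15 with an estimated correlation). Slow fibre genes were lower, Tnnc1 (-3.99 ± 0.43), Myl2 (-3.85 ± 0.40), Tnnt1 (-3.59 ± 0.34) and Atp2a2 (-3.21 ± 0.24). None of the 15 lists that passed held with an estimated correlation. In the C57BL10 TA 491 probe sets passed, 182 higher and 309 lower, but 1457 higher and 486 lower without a filter, and 498 higher and 395 lower with a filter on the highest group mean. Quantile normalization gave 1668 and array weights 9. With a period block 49 passed. Without 1 C57BL10 array there were 273 (diaphragm sample 1), 242 (diaphragm sample 2), 311 (EDL sample 1) and 261 (gastroc sample 2). There were also 301 (quadriceps sample 1), 306 (quadriceps sample 2), 276 (soleus sample 1), 2672 (TA sample 1) and 61 (TA sample 2). Quantile normalization moved the median of all probe sets from 0.01 to -0.20.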

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

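All tests of explanations here were chosen after the results were seen, except the test of a common source in C57BL10 TA and the tests of other splits of the arrays. A test of the difference between muscles set apart the change in the diaphragm from the mean change in the limb muscles for 17 probe sets, and a joint test over the 6 muscles did so for 50. In the first test the difference was 2.77 for Comtd1, 2.45 for Gadd45b, 2.35 for Myl4 and 2.13 for Tnc (log2). It was -3.12 for Pcbd1, -2.53 for Cyp4v3, -1.98 for Cpt1a, -1.82 for Csad and -1.78 for Ccl9.

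Liver transcripts stood in the diaphragm arrays of all strains and, at lower levels, in the TA arrays, most of all in C57BL10 (list mean 10.99, against 7.95 in C57BL10 gastroc), and in mdx quadriceps sample 1 and mdx5cv quadriceps sample 2. Scaling of the deposited values is argued against, since the liver list was still 6.43 (log2) higher in the C57BL10 diaphragm than in the limb muscles after quantile normalization. A later list of liver genes, none on the fixed list, had a median of 4.95. All 24 values were positive (14 genes were tested), which goes with RNA from liver as a candidate source. Alb and Apoa1 had signals of 94590 and 66918 there and of 141 and 111 in C57BL10 EDL, gastroc and soleus, muscles where 7 of the 12 and 16 of the 24 genes lay above the floor. Across liver genes, which are not independent, the rise in C57BL10 TA followed that in the diaphragm (Spearman 0.846), so both may share a source. Transcription by the diaphragm itself stays open, since the like gene order in C57BL10 and mdx5cv diaphragm (Spearman 0.922) follows from either source. It alone would not give the raised TA and quadriceps levels.

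Slow fibre transcripts were 2.09 (log2) higher in mdx5cv EDL than in mdx EDL. An exchange of the EDL and soleus samples of mdx5cv is argued against, since the soleus share of the mdx5cv soleus arrays was 0.894 (95% bootstrap interval over probe sets 0.822 to 1.01), and from soleus-high and EDL-high probe sets 0.789 and 1.05 in sample 1 and 0.813 and 1.10 in sample 2. Soleus tissue in the EDL samples is undecided, since 74 soleus-high probe sets gave a share of 0.0389 (-0.0143 to 0.113) and 42 EDL-high ones 0.272 (0.131 to 0.395). The 13 slow fibre genes had a median share of 0.235, from -0.187 for Mb to 0.421 for Myl2. A shift to slow fibres in mdx5cv limb muscle in general, the biological explanation, is open as well, with a mean of 0.405 over gastroc, quadriceps and TA, since its interval (0.0747 to 0.746, bootstrap over genes regulated together) holds no spread between samples and the gastroc had 1 array per mutant.

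The genes that differ between mdx5cv and mdx are not explained by the scanning period alone, since 97.4% of the probe sets (38 of 39) passed in the same direction with the period as a block. In fits of the mutant arrays of 1 period alone, 6 passed within the second, of which 6 had the same direction within the third, and 4 within the third, of which 4 had it within the second. Linked strain variants outside Dmd are undecided: 10 of 33 placed genes had another such gene among the 20 nearest on either side, against a median of 6 in 10000 random draws (permutation p = 0.169). A background of mdx5cv apart from both other strains is open too, as C57BL10 was nearer mdx for 43.6% of the probe sets (95% Clopper-Pearson interval 27.8 to 60.4). The intervals for this share and for the soleus share were made a criterion after their values were seen, which moved both explanations from excluded to open.

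Other splits of the arrays were set against the real one, 100 for each mean comparison of strains, the real one included. For mdx against C57BL10, chance can be excluded: 1 split reached the real count of 1182, and the highest other was 585, from a split that keeps the real labels of 21 of 23 arrays (the next was 138). Such a division can be excluded for mdx5cv against C57BL10 as well, with 1 split at the real count of 1112 and 12 as the highest other. For mdx5cv against mdx, 2 splits reached the real count of 39. The highest other had 108, from a cause not identified, so chance is not firmly excluded. That split put 4 and 5 arrays of the second period on its sides, and the next highest had 12. Within the third period, C57BL10 arrays in the fit, 10 probe sets differed between mdx5cv and mdx, and with the period as a block 81.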

How the results depend on the processing

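Tests with other handling of the identical columns, the low-correlation arrays, the scanning period and the muscles in the mean, and gene lists and shared counts without 1 array, were chosen after the data were seen, and the other settings before. The counts for mdx against C57BL10 (1182) and mdx5cv against C57BL10 (1112) stayed within 1.5 times under every setting except the 2-against-2 means and the third period alone. Leaving out 1 array gave 949 to 1554 and 932 to 1389 for them. The counts that moved for single muscles and for differences between muscles follow, and the cause was not tested except where fewer arrays show it. Over the gene results, leaving out 1 array kept 7666 on the same side of the threshold, ended 894 calls, added 1 and turned 13. Quantile normalization kept 556 and ended 68, the period block kept 484 and ended 146, and leaving out the 2 low-correlation arrays kept 564 and ended 65. No filter kept 591 and ended 41, a floor at the 5th percentile kept 608 and ended 14, and a prior variance without a trend kept 604 and ended 28. The minimum fold of 1.5, the fit of 2 strains only and the strain and sample number as a random block (correlation 0.0538) left every count within 1.5 times. A floor at signal 118 hides changes between levels below it.

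Quantile normalization gave counts of 259 in quadriceps and 874 in TA for the mutants against C57BL10, 45 in quadriceps and 1668 in TA among C57BL10 muscles. Without a filter there were 515 in TA for the mutants against C57BL10, 1943 in TA among C57BL10 muscles, 11 for diaphragm against limb, with a filter on the highest group mean 893 in TA among C57BL10 muscles, and with the brightest probe set of each gene, which tests fewer probe sets, 42 in gastroc and 51 in quadriceps among C57BL10 muscles. The scan day as a random block (correlation 0.358) gave 21 for mdx5cv against mdx, 110 in diaphragm, 426 in EDL, 253 in gastroc, 626 in quadriceps, 219 in soleus and 93 in TA for the mutants against C57BL10, 732 in diaphragm, 297 in soleus and 38 in TA among C57BL10 muscles, 3 for diaphragm against limb and 31 for the joint test. The period as a fixed block gave 81 for mdx5cv against mdx, 62 in diaphragm, 620 in quadriceps and 116 in TA for the mutants against C57BL10, 49 in TA among C57BL10 muscles, 3 for diaphragm against limb and 26 for the joint test. The arrays with an experiment file and no block, which are fewer, gave 103 in diaphragm and 90 in TA for the mutants against C57BL10, 774 in diaphragm, 50 in quadriceps and 44 in TA among C57BL10 muscles, 3 for diaphragm against limb and 21 for the joint test. Means over the muscles, 2 against 2, gave 413 for mdx and 387 for mdx5cv against C57BL10 and 11 for mdx5cv against mdx. Here fewer values enter the test, and the muscles are not counted as independent. The third period alone gave 186 for mdx against C57BL10, 271 for mdx5cv against C57BL10 and 10 for mdx5cv against mdx, and the second 6 for mdx5cv against mdx, both with fewer arrays. Against the other 4 limb muscles, the counts were 28 in EDL, 4 in gastroc and 5 in quadriceps among C57BL10 muscles. All 36 columns gave 346 in gastroc for the mutants against C57BL10. The gastroc copies in place of the quadriceps copies gave 377 in gastroc and 535 in TA for the mutants against C57BL10, 1063 in TA among C57BL10 muscles, 27 for diaphragm against limb and 100 for the joint test. With both copies left out there were 526 in TA for the mutants against C57BL10, 98 in gastroc and 1172 in TA among C57BL10 muscles, 29 for diaphragm against limb and 86 for the joint test. Without the 2 low-correlation arrays the counts were 457 in diaphragm, 363 in EDL, 288 in gastroc, 208 in soleus and 173 in TA for the mutants against C57BL10, 1832 in diaphragm, 189 in EDL, 101 in gastroc, 116 in quadriceps, 299 in soleus and 86 in TA among C57BL10 muscles, 49 for diaphragm against limb. Array weights gave 1138 in diaphragm, 401 in EDL, 358 in gastroc, 255 in soleus and 15 in TA for the mutants against C57BL10, 2578 in diaphragm, 199 in EDL, 159 in gastroc, 340 in quadriceps, 375 in soleus and 9 in TA among C57BL10 muscles, 154 for diaphragm against limb and 82 for the joint test. With an estimated correlation, the number of lists past the threshold went from 15 to 8 in mdx, from 17 to 9 in mdx5cv and from 8 to 0 for mdx5cv against mdx. Split controls, which are fewer, gave 365 and 356 probe sets shared higher and 58 and 55 shared lower.

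Leaving out 1 array in turn gave counts of 30 to 62 for mdx5cv against mdx, 3 to 31 for diaphragm against limb and 24 to 723 for the joint test. For the mutants against C57BL10 these were 73 to 210 in diaphragm, 88 to 164 in EDL, 74 to 100 in gastroc, 162 to 733 in quadriceps, 38 to 111 in soleus and 123 to 2070 in TA, and among C57BL10 muscles 538 to 1612 in diaphragm, 46 to 294 in EDL, 5 to 145 in gastroc, 10 to 205 in quadriceps, 65 to 317 in soleus and 61 to 2672 in TA. Among 210 list results past the threshold 77 ended without some array, as did 26 of the 84 that held with an estimated correlation. Gene values that turned sign were as follows. Dmd, effect in diaphragm against mean effect in 5 limb muscles, was 0.20 and became -0.15 to 0.55 with 1 array left out. Dmd, mdx5cv against mdx, mean over 6 muscles, was 0.25 and became -0.19 within the second period. Tat, mdx5cv against C57BL10, mean over 6 muscles, was -0.87 and became 0.22 within the third period, which holds no C57BL10 diaphragm or TA array. Utrn, C57BL10 TA against the other 5 muscles, was -0.14 and became -1.27 to 0.99 with 1 array left out. Utrn, C57BL10 diaphragm against the other 5 muscles, was -0.18 and became 0.049 without the 2 low-correlation arrays and -0.40 to 0.049 with 1 array left out. Utrn, C57BL10 gastroc against the other 5 muscles, was -0.20 and became 0.10 with the scan day as a random block, 0.045 with the period block and over the arrays with an experiment file, 0.025 without the 2 low-correlation arrays and -0.43 to 0.025 with 1 array left out. Utrn, dystrophin-deficient against C57BL10 in EDL, was -0.051 and became 0.0086 with the scan day as a random block and -0.36 to 0.26 with 1 array left out. Utrn, dystrophin-deficient against C57BL10 in TA, was -0.14 and became 0.17 with quantile normalization, 1.18 with the scan day as a random block, 1.13 with the period block and over the arrays with an experiment file, 1.00 without the 2 low-correlation arrays and -1.27 to 1.00 with 1 array left out. Utrn, dystrophin-deficient against C57BL10 in soleus, was -0.00070 and became 0.00067 with quantile normalization and -0.25 to 0.25 with 1 array left out. Utrn, mdx5cv against mdx, mean over 6 muscles, was 0.063 and became -0.091 with quantile normalization, -0.065 with the scan day as a random block, -0.028 over the arrays with an experiment file, -0.015 without the diaphragm, -0.00011 without both copies and -0.020 to 0.15 with 1 array left out. The cause was not tested.

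The labels do not say that equal sample numbers pair the samples, and a check of this pairing does not settle it. In that check, the correlation of residuals of same-numbered samples was over 0.1 in 9 of 15 pairs of strains within a muscle (-0.23 to 0.41) and in 16 of 35 pairs of muscles within a strain (-0.35 to 0.40). With the replicate block the counts were 1202 for mdx and 1094 for mdx5cv against C57BL10, 36 for mdx5cv against mdx and 743 for C57BL10 TA, and 4 lists passed for mdx5cv against mdx. The cause was not tested.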

Other observations

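Tests on clock genes, on chromosomes and on differences between scanning periods were chosen after the data were seen, and the gene lists of this paragraph before. Rises were seen for the metallothioneins Mt2 (2.25 ± 0.13) and Mt1 (1.39 ± 0.15) and the chaperone Hsp90aa1 (0.49 ± 0.12) in mdx, and Mt2 (2.16 ± 0.13) and Mt1 (1.03 ± 0.15) and Hsp90aa1 (0.66 ± 0.12) in mdx5cv. Of that chaperone list Hmox1 (0.45 ± 0.12) rose in mdx too, and Hspa9 (-0.51 ± 0.16, adjusted p = 0.067 without mdx5cv diaphragm sample 2) fell in mdx5cv. The list as a whole did not pass in mdx (adjusted p = 0.28, adjusted p = 0.63 with an estimated correlation) or in mdx5cv (adjusted p = 0.65, adjusted p = 0.92 with an estimated correlation). Of the vessel genes, the endothelial Cldn5 (0.93 ± 0.14) and Flt1 (-0.61 ± 0.16) and the smooth muscle genes Acta2 (1.02 ± 0.18) and Myh11 (-0.90 ± 0.21) changed in mdx, and Cldn5 (1.22 ± 0.14), Flt1 (-0.89 ± 0.16) and Acta2 (1.10 ± 0.18) in mdx5cv. The endothelial list had an adjusted p of 0.66 in mdx and 0.82 in mdx5cv.

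On a list of clock genes written after such genes were seen among the leading differences, and not tested as a list, Arntl (1.13 ± 0.16) was higher in mdx5cv than in mdx and Dbp (-1.41 ± 0.19), Per2 (-1.41 ± 0.20), Tef (-0.79 ± 0.18) and Usp2 (-0.71 ± 0.15) were lower, Tef with an adjusted p of 0.12 without mdx5cv EDL sample 2 and Usp2 with 0.054 without mdx5cv diaphragm sample 2. Clock, Cry1, Cry2, Per1, Per3, Nr1d1, Nr1d2, Nfil3 and Bhlhe40 did not pass. In mdx5cv against C57BL10, Arntl (0.58 ± 0.15) was higher and Per2 (-1.84 ± 0.19), Dbp (-1.29 ± 0.18), Per1 (-1.06 ± 0.21), Nr1d2 (-0.67 ± 0.15) and Usp2 (-0.63 ± 0.14) were lower, as were Tef (-0.60 ± 0.17; adjusted p = 0.054 without C57BL10 EDL sample 1) and Nr1d1 (-0.54 ± 0.16; adjusted p = 0.058 without C57BL10 EDL sample 1). In mdx Arntl (-0.55 ± 0.15) and Nr1d1 (-0.61 ± 0.16) were lower and Bhlhe40 (0.38 ± 0.12; adjusted p = 0.082 without mdx EDL sample 1) was higher. The labels give no time of day for the dissections.

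With each gene represented by its probe set of highest mean, of the 33 genes with a position that differ between mdx5cv and mdx, 6 lie on the X chromosome, which holds Dmd and 155 of the 5687 tested genes (Fisher's exact test over 21 chromosomes, p = 2.2e-04, adjusted p = 0.0047, 0.051 without mdx quadriceps sample 1). Of these Mid1ip1 (-0.96), Nono (-0.77), Ogt (-0.73) and Hprt (-0.69) were lower in mdx5cv (log2), and Erdr1 (2.87) and Mtm1 (0.52) higher, Mtm1 with an adjusted p of 0.088 without mdx5cv diaphragm sample 2. Atp7a, also on the X chromosome, is not counted, since its probe set of highest mean did not pass and another did (-0.89).

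Between scanning periods, limma found 383 probe sets different between the second and the third period over 20 mutant arrays (1674 at an unadjusted p under 0.05). Between the first and the third period over 9 C57BL10 arrays limma found 0, with 1020 at an unadjusted p under 0.05.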
